A study of Mus musculus with 24 samples.

How the data were processed

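The series holds 24 RNA-seq libraries of mouse bone marrow-derived macrophages, 1 library for each of 24 conditions. Per the labels, the cells were grown in L929-conditioned medium, primed for 8 h with PBS, LPS (100 ng/mL) or IFN-γ (100 ng/mL), washed free of the priming stimulus, rested for 66 h and then stimulated again with LPS (0.1 ng/mL) for 0, 1.5 or 3 h. Macrophages are labelled wild type (WT), Irf1-/- and Ifnar-/-, and IFN-γ priming is present only for WT and Irf1-/-. The 8 combinations of genotype and priming are called groups here, and each group has 3 libraries, 1 per time. No condition was sequenced more than once. The labels give 1 genotype per culture and do not say which animals gave which library, so genotype cannot be separated from animal or culture. Nothing says that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples.

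Per the labels, RNA was selected by polyadenylation and read as pairs on a BGI machine. The submitters' processing notes name STAR, SAMtools, featureCounts and Subread, without versions, and the mm10 genome. The gene annotation, the strand setting and the level at which reads were counted are not given in the sources used here, and fields for the source molecule read as genomic, which is odd for an RNA series and was left as it stands. The deposited table holds integer read counts for 29700 genes in the 24 libraries, and all fits here start from those counts. The authors' sequence reads were not used here. Gene positions come from GENCODE M21 on GRCm38, the same assembly as mm10, matched by gene name. Without the strand and annotation used for counting, reads shared by neighbouring or overlapping genes, for example Gbp4 and Gbp8 or Tnfsf13os and Tnfsf13, cannot be assigned with certainty, and the same holds for close paralogs such as the Oas1, Gbp, Ifit3, Tgtp and H2 genes.

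Column totals ran from 19.66 to 20.61 M counts, 12668 to 13164 genes had at least 10 counts in a library, and mitochondrially encoded transcripts took 1.18% to 2.05%. The 10 most abundant genes took 13.7% to 17.8%. No 2 libraries were copies of each other: the closest pair of 276 differed with a chi-square of 9.12 per degree of freedom. Genes were kept at 0.497 CPM (counts scaled to library size) or more in at least 3 libraries with a total of at least 15, which kept 13821 genes and 99.9% of counts. There were 2172 genes with 0 counts throughout. 1 count is 0.0497 CPM in the median library.

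Normalisation was TMM, with factors from 0.945 to 1.04. The test was edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment, and a gene was called at adjusted p under 0.05. 2 designs were fitted to all libraries. The first has 1 term per group and 1 per time (14 residual degrees of freedom, prior 4.91, biological coefficient of variation 0.110), and it compares groups over the 3 times. The second has 1 term per group, a response to re-stimulation (1.5 and 3 h against 0 h) per group and a shared shift from 1.5 to 3 h (7 residual degrees of freedom, prior 5.12, coefficient 0.103). It fits the 0 h libraries exactly, and its error comes only from 1.5 h against 3 h. In both, the error is the departure of single libraries from an additive pattern, so a true interaction of priming with time counts as error. Differences between genotypes in a priming effect are contrasts of 4 groups in the first design. Values are log2 fold changes ± standard error, positive where the group named first is higher. The designs, the gene lists, the rule for naming genes and all alternatives except 2 were chosen before the data were examined. The 2 exceptions, leaving out 1 library and removing a gene length trend, were chosen after that library had been seen.

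Genes are named by a fixed rule: called, the same sign at all 3 times, at least 5 CPM in the higher group and not a predicted gene, taking the 10 largest rises and falls per comparison (8 for responses) and up to 4 members per list with the smallest p. The text names fewer. Where a gene had 3 or fewer counts in a group, its ratio of counts is given with an interval from counting or, at 0 counts, as at least a ratio against a floor of 3 counts.

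Gene lists were written from general knowledge: type I interferon-stimulated genes, IFN-γ-induced GTPases and effectors, MHC class I and class II presentation, interferon pathway receptors and transcription factors, LPS-induced inflammatory mediators, negative regulators of LPS signalling, TLR4 pathway components, antimicrobial effectors, cell death and inflammasome, cholesterol synthesis, glycolysis and hypoxia, proliferation, alternative activation, heat shock and stress, mitochondrially encoded transcripts, genes flanking Irf1 and Ifnar1, sex-linked genes, and markers of macrophages, neutrophils, dendritic cells, T and NK cells, B cells, mast cells, fibroblasts and erythroid cells. Of these, 22 lists had at least 5 tested members. They were tested with fry in the 14 group comparisons, adjusted over all 308 tests. Camera with an estimated correlation between genes was the main alternative, and its adjusted p is printed where it loses a fry call. "Over the list alone" means that gene p-values were adjusted within the list.

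To check the tests, counts were simulated from 1 mean profile with these library sizes and the spread fitted here. They had no effects of time, no interactions and no outlying library, so the shares may not hold for the real libraries. Of genes with planted changes of 1.5-, 2- and 4-fold, 47.8%, 76.1% and 87.9% were called for the LPS priming contrast. There were 6 false calls among 13821 genes. For the genotype difference in IFN-γ priming the shares were 31.3%, 64.2% and 86.4% with 9 false calls, for the response in PBS-primed WT 11.9%, 47.8% and 89.4% with 6, and for a difference of responses 1.49%, 19.4% and 77.3% with 2. A gene absent from a list of calls may thus still have changed, even by 4-fold, most of all in response differences (51 of 66 such genes called). In lists without planted changes, 32 of 308 fry tests had p under 0.05 and 0 passed adjustment. For the overlap of the 2 primings, the PBS-primed WT libraries were drawn along with the primed ones in each simulation, since real controls set against draws from their own fitted means share no chance values. This was a change from the plan, made after the data were seen. A length trend planted in all 3 LPS-primed Ifnar-/- libraries gave 31 false calls for LPS priming in Ifnar-/-, and 3 after the trend was removed. A trend in 1 library alone was not simulated. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.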

Results

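Irf1 (GRCm38 chromosome 11, 53770014 to 53778374, protein-coding), which encodes an interferon-induced transcription factor, kept its counts in the libraries labelled Irf1-/-, lower than in WT at some times and higher at others. In PBS-primed cells it stood at 34.6, 319 and 228 CPM at 0, 1.5 and 3 h in WT and at 40.7, 220 and 218 CPM in the libraries labelled Irf1-/-. After LPS priming it had 57.6, 176 and 87.4 CPM in WT and 59.1, 129 and 103 CPM with the label. After IFN-γ priming the values were 227, 986 and 507 CPM in WT and 366, 743 and 628 CPM in the libraries so labelled (n = 1 library per value). Over the 3 times Irf1 was not called between the label and WT, at -0.18 ± 0.37 after PBS (adjusted p = 0.92), -0.06 ± 0.38 after LPS (adjusted p = 0.999) and 0.24 ± 0.37 after IFN-γ (adjusted p = 0.896). Ifnar1 (chromosome 16, 91485238 to 91507441, protein-coding), a chain of the type I interferon receptor, had 48.4 to 58.2 CPM in the 6 libraries labelled Ifnar-/- and 124 to 188 CPM in the other 18. The mRNA values thus give no support for a loss of Irf1 transcript, and everything below written about Irf1-/- refers to the label.

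**Figure D1:**
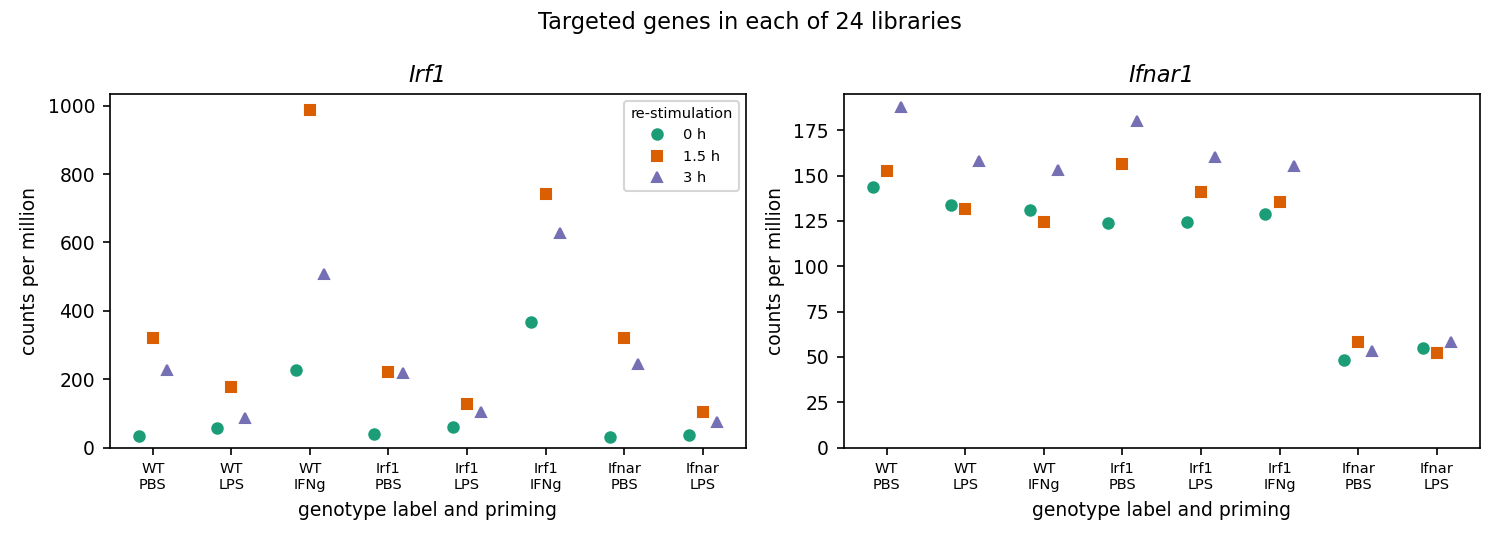
Irf1 and Ifnar1 in CPM in each of the 24 libraries, by genotype label, priming and time of re-stimulation. Each point is 1 library.

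All libraries carried a macrophage profile. Lyz2, the lysozyme gene of myeloid cells, had 28849 to 47400 CPM. Cd3e, a T cell receptor component, had 0 counts, and Cd79a, of the B cell receptor complex, had 20 counts in all libraries together. Of the T and NK cell markers 3 of 16 in the table passed the expression filter, and of the B cell markers 4 of 15. For mast cell markers it was 1 of 9, for erythroid markers 1 of 8 and for sex-linked genes 1 of 2, so these lists were not tested. Xist, the transcript of the inactive X chromosome, had 213 to 393 CPM in every library, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were not in the table. Fibroblast transcripts were present at low level, with Col1a1, a collagen chain, at 1.46 to 21.0 CPM and Acta2, smooth muscle actin, at 7.60 to 117 CPM. The fibroblast and stromal list (11 measured) was called in 0 of 14 comparisons by fry, with a lowest adjusted p of 0.0522 for LPS priming in WT. There 3 of its genes rose and 0 fell (3 over the list alone, median 0.98), and with IFN-γ priming in WT 0 did in edgeR (2 higher over the list alone, adjusted p = 0.116, median 1.02). A shift in a few contaminating cells with priming is thus not excluded.

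The first component of the 24 libraries took 26.2% of the variance and the second 18.7%. On the first, the 0 h libraries lay at 17.9 to 47.2 and the 1.5 h libraries at -4.57 to -16.5, with 1 exception: the LPS-primed Ifnar-/- library at 1.5 h lay at 33.2, among the unstimulated ones. This library also carried a gene length trend, -0.134 log2 units per doubling of length against -0.067 to 0.064 in the others. Counts of called genes that involve it are given with and without it below, while list tests and values of single genes include it unless stated. All libraries share 1 fit, so it also bears on other comparisons. Without it, calls for IFN-γ and LPS priming in WT went from 652 to 916 and from 1908 to 2606. For the Irf1-/- label against WT after IFN-γ they went from 819 to 1067.

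**Figure D2:**
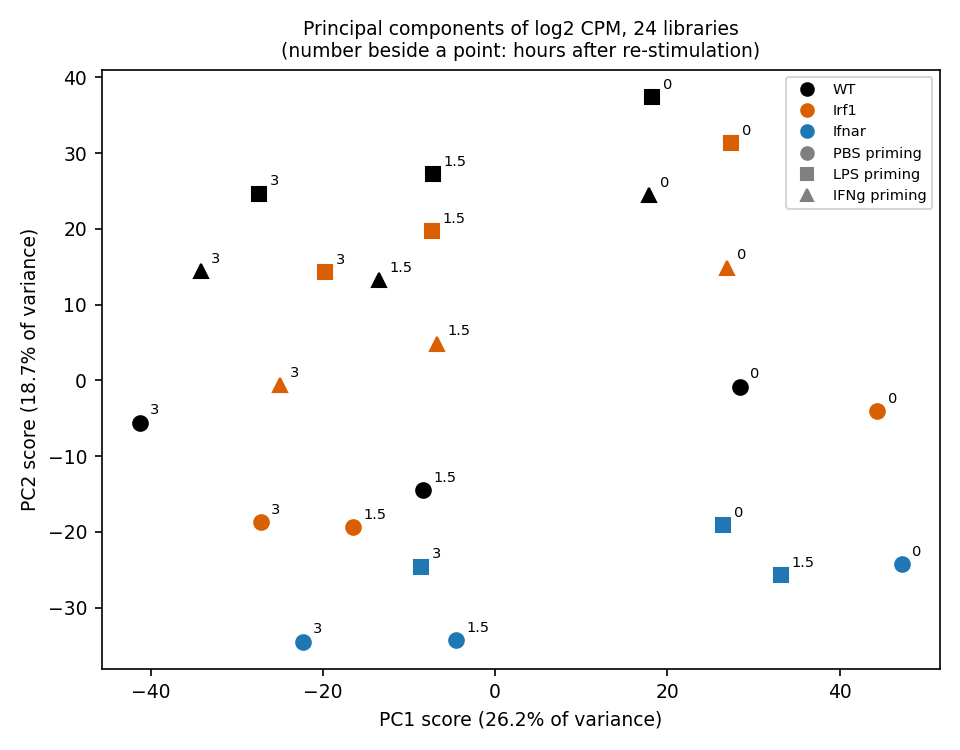
First 2 principal components of the 24 libraries. The LPS-primed Ifnar-/- library at 1.5 h lies among the libraries without re-stimulation.

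IFN-γ-primed WT macrophages showed an interferon program over the 3 times: 451 genes were higher and 201 lower than in PBS-primed WT (n = 3 libraries per group, 1 per time). As in all group comparisons here, 2 of the 3 times follow re-stimulation. The counts thus do not separate a state kept through the 66 h of rest from a changed reaction to the second LPS. At 0 h alone, 289 genes called higher on the other 2 times had a median effect of 0.68, without a test. The largest rises were those of Gbp4, a guanylate-binding GTPase (7.17 ± 0.50, adjusted p = 9.8e-09, 144-fold), and Iigp1, an immunity-related GTPase (7.08 ± 0.42, adjusted p = 5.9e-09). Cxcl9, a T cell chemokine, rose by 6.46 ± 0.52, from 0.065 to 6.41 CPM. Tgtp2, a further immunity-related GTPase (5.74 ± 0.37), Zbp1, a sensor of Z-form nucleic acids (4.68 ± 0.30), Ly6a, a surface antigen (4.07 ± 0.23), Gbp6 (3.95 ± 0.37) and Gvin3, a very large interferon-induced GTPase (3.81 ± 0.37), followed. Il12rb1, a chain of the IL-12 receptor, rose by 3.37 ± 0.26 to 7.59 CPM (adjusted p = 3.8e-08), and Gbp8 by 3.15 ± 0.21. Gbp4, Gbp6 and Gbp8 lie side by side on chromosome 5 (105014150 to 105293698), and Gbp8 overlaps Gbp4 on the same strand. Gbp4 averaged 0.151 CPM in PBS-primed WT, so its fold is loose.

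Falls in IFN-γ-primed WT were smaller. Serpinb1a, an inhibitor of neutrophil proteases, fell by 1.71 ± 0.17 (adjusted p = 1.6e-06). Tox2, an HMG-box factor, fell by 1.33 ± 0.16, Fbln5, an extracellular matrix protein, by 1.28 ± 0.20 and Itgb3, the integrin β3 chain, by 1.02 ± 0.09 (adjusted p = 2.0e-07). Tns1, a focal adhesion protein, fell by 0.95 ± 0.10 and Pcp4l1 by 0.91 ± 0.11.

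By function, antigen presentation and interferon effectors led the change in IFN-γ-primed WT. All 22 measured MHC class I genes rose and 0 fell (22 over the list alone, fry adjusted p = 2.6e-08). Among them were Tap1, the peptide transporter (2.00 ± 0.11), H2-T23 (1.81 ± 0.11), Nlrc5, the class I transactivator (1.84 ± 0.13), and H2-K1 (1.23 ± 0.10). Of 12 MHC class II genes 9 rose, 0 fell and 3 did not pass (10 over the list alone, adjusted p = 2.7e-08). H2-Aa rose by 2.28 ± 0.14, H2-Ab1 by 2.19 ± 0.17, the peptide editor H2-DMa by 1.92 ± 0.13 and the protease Ctss by 1.08 ± 0.07. Of 33 IFN-γ-induced GTPases and effectors 29 rose and 4 did not pass (32 over the list alone, adjusted p = 2.0e-08). Of 40 type I interferon-stimulated genes 22 rose and 18 did not pass (31 over the list alone, adjusted p = 6.5e-05). Among them was Oas3, a 2'-5' oligoadenylate synthase (1.76 ± 0.09). In the list of 32 interferon receptors and transcription factors 11 rose and 0 fell (14 and 1 over the list alone, adjusted p = 1.2e-05). Irf9 and Stat2, partners in the ISGF3 complex, rose by 0.73 ± 0.09 and 0.97 ± 0.16 and Batf2 by 1.93 ± 0.30.

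Cholesterol synthesis moved the other way in the same cells: 13 of 23 genes fell, 0 rose and 10 did not pass (19 over the list alone, adjusted p = 7.6e-07). Among them was Sqle, squalene epoxidase (-0.51 ± 0.06). Antimicrobial effectors rose for 6 of 22 with 0 lower (8 over the list alone, adjusted p = 0.000522), with Irgm1 at 2.15 ± 0.27 and Gbp2 at 2.89 ± 0.45. Cell death genes rose for 8 of 33 with 0 lower (9 over the list alone, adjusted p = 0.000107), with Casp12 (4.01 ± 0.47), Casp1, the inflammasome protease (0.76 ± 0.10), and Tnfsf10, the death ligand TRAIL (2.48 ± 0.35). Macrophage markers rose for 6 of 22 and fell for 1 (9 and 1 over the list alone, adjusted p = 3.0e-05), with the Fc receptor Fcgr1 at 1.14 ± 0.11 and Aif1 at 1.58 ± 0.19. Glycolysis and hypoxia genes rose for 4 of 23 with 0 lower (6 over the list alone, adjusted p = 0.000314, adjusted p = 0.0619 with an estimated correlation), led by Vegfa, an angiogenic factor (1.33 ± 0.13). Proliferation genes fell for 5 of 36 with 0 higher (16 over the list alone, adjusted p = 0.00227, adjusted p = 0.0964 with an estimated correlation). Dendritic cell markers rose for 1 of 8 with 0 lower (2 over the list alone, adjusted p = 0.0439, adjusted p = 0.533 with an estimated correlation). Of 33 LPS-induced inflammatory mediators only 2 rose and 0 fell (2 over the list alone, adjusted p = 0.605). The 29 negative regulators of LPS signalling had 0 rises and 1 fall (0 and 1 over the list alone, adjusted p = 0.851) and the 34 TLR4 pathway components had 0 of either in edgeR (0 over the list alone, adjusted p = 0.892). The total of 652 calls was 359, 412 and 233 without the 0, 1.5 and 3 h libraries and 1133 when only the compared libraries were fitted.

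LPS priming changed more genes in WT than IFN-γ priming did, 1111 higher and 797 lower than in PBS-primed WT (n = 3 libraries per group), and interferon-stimulated genes were frequent among the largest rises. Ccl5, a chemokine of late LPS responses, rose from 19.96 to 1140 CPM (6.85 ± 1.03, adjusted p = 0.000127). Its means in Ifnar-/- libraries, 663 CPM after LPS and 33.1 CPM after PBS priming, are given without a test and include the library that stood apart. Ifi213 (6.64 ± 0.53), Ifi209 (4.73 ± 0.28, adjusted p = 1.3e-09) and Ifi206 (4.71 ± 0.41), nucleic acid sensor genes of the interferon-inducible cluster on chromosome 1 (173468485 to 173647928), rose together. Ifi44 rose by 5.67 ± 0.40, Zbp1 by 4.53 ± 0.30, Oas1g by 4.23 ± 0.23, Oasl2 by 3.85 ± 0.25 and Ifit3 by 3.85 ± 0.60. Irf7, the transcription factor that amplifies interferon production (chromosome 7, 141262706 to 141266481), rose from 8.77 to 193 CPM (4.48 ± 0.28, adjusted p = 1.7e-09). Falls repeated several seen with IFN-γ: Tox2 (-1.70 ± 0.17), Fbln5 (-1.48 ± 0.20), Serpinb1a (-1.31 ± 0.17), Pcp4l1 (-1.30 ± 0.11) and Itgb3 (-1.21 ± 0.09, adjusted p = 1.5e-08). Ednrb, an endothelin receptor, fell by 1.33 ± 0.22 and Hyal1, a hyaluronidase, by 1.16 ± 0.19.

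By the share of genes called, the lists of LPS-primed WT were led by type I interferon-stimulated genes, where 38 of 40 rose and 2 did not pass (40 over the list alone, adjusted p = 9.4e-08). MHC class I genes rose for 19 of 22 with 0 lower (20 over the list alone, adjusted p = 1.5e-07), with H2-T24 at 2.80 ± 0.18 and H2-D1 at 1.15 ± 0.09. IFN-γ-induced GTPases rose for 20 of 33 with 0 lower (24 over the list alone, adjusted p = 5.9e-06). Interferon receptors and transcription factors rose for 10 of 32 with 2 lower (11 and 2 over the list alone, adjusted p = 1.9e-05). Cholesterol synthesis fell for 19 of 23 with 0 higher (21 over the list alone, adjusted p = 1.7e-08), including Sqle (-0.60 ± 0.06) and Insig1, a brake on sterol synthesis (-0.95 ± 0.10). Macrophage markers rose for 11 of 22 and fell for 1 (11 and 1 over the list alone, adjusted p = 8.0e-07), with Cx3cr1, the fractalkine receptor, at 1.88 ± 0.16 and Adgre1, which encodes F4/80, at 0.97 ± 0.10. Antimicrobial effectors rose for 9 of 22 with 0 lower (9 over the list alone, adjusted p = 3.4e-05), with Slpi, a protease inhibitor (2.16 ± 0.21), haptoglobin Hp (1.76 ± 0.26) and ceruloplasmin Cp (2.04 ± 0.35).

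Further fry calls in LPS-primed WT were weaker under camera. MHC class II rose for 8 of 12 and fell for 1 (9 and 2 over the list alone, adjusted p = 0.000250, adjusted p = 0.0964 with an estimated correlation). Proliferation fell for 20 of 36 with 0 higher (24 over the list alone, adjusted p = 0.000275, adjusted p = 0.0964 with an estimated correlation), with the cyclin Ccna2 at -0.45 ± 0.07. Heat shock and stress genes rose for 9 of 29 and fell for 1 (10 and 2 over the list alone, adjusted p = 0.000199, adjusted p = 0.105 with an estimated correlation), with Ddit3, a factor of the integrated stress response, at 1.24 ± 0.15 and heme oxygenase Hmox1 at 0.54 ± 0.07. Cell death genes rose for 11 of 33 and fell for 1 (13 and 1 over the list alone, adjusted p = 0.000346, adjusted p = 0.113 with an estimated correlation). Alternative activation genes fell for 8 of 19 and rose for 2 (10 and 2 over the list alone, adjusted p = 0.00179, adjusted p = 0.169 with an estimated correlation), with the mannose receptor Mrc1 at -1.05 ± 0.18. Dendritic cell markers rose for 3 of 8 and fell for 1 (3 and 1 over the list alone, adjusted p = 0.000183, adjusted p = 0.183 with an estimated correlation), with the homing receptor Ccr7 at 2.95 ± 0.59. Mitochondrially encoded transcripts fell for 3 of 13 with 0 higher (4 over the list alone, adjusted p = 0.00827, adjusted p = 0.269 with an estimated correlation). Neutrophil markers rose for 4 of 13 with 0 lower (4 over the list alone, adjusted p = 0.0181, adjusted p = 0.393 with an estimated correlation). Of 33 LPS-induced mediators 6 rose and 1 fell (8 and 3 over the list alone, adjusted p = 0.5), with a median of -0.04 and a mean of 0.30. The total of 1908 calls was 976 and 659 without the 0 and 3 h libraries and 3380 when only the compared libraries were fitted. In that last fit 1631 genes were higher and 1749 lower, so the excess of rises was lost.

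For the 2 primings in WT, 461 genes were called in the same direction, 311 higher and 150 lower, and 10 in opposite directions. Independent calls would share 47.8, from 36.3 higher and 11.6 lower. In 20 simulations of unchanged groups with shared controls edgeR called 0 genes for either priming, so the simulated shared count of 0 is no reference for the 461. The log2 changes correlated at 0.704 against 0.497 in the simulations, with a covariance of 0.159 against 0.0356, which leaves 0.124. Both primings are set against the same PBS-primed libraries, so part of the excess may come from these shared controls. At adjusted p under 0.01 there were 236 shared genes with 15.5 under independence.

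Set against each other, IFN-γ-primed WT had 230 genes higher and 351 lower than LPS-primed WT (n = 3 libraries per group). Higher after IFN-γ were Iigp1 (4.20 ± 0.33), Gbp4 (4.07 ± 0.36, adjusted p = 7.4e-07), Ciita, the class II transactivator (3.50 ± 0.31, adjusted p = 7.4e-07), Tgtp2 (3.42 ± 0.31), Gbp8 (2.56 ± 0.20), Calhm6, an ion channel gene (2.31 ± 0.31), and Il12rb1 (2.27 ± 0.23). Lower were Irf7 (-3.14 ± 0.25, adjusted p = 2.3e-07), Ifi213 (-2.84 ± 0.35), Bcl2a1a, a survival factor (-2.81 ± 0.45), Oas1g (-2.68 ± 0.20), Ifi206 (-2.64 ± 0.33), Cd55, a complement regulator (-2.56 ± 0.37), and Ifi44 (-2.49 ± 0.29). Type I interferon-stimulated genes were lower for 24 of 40 and higher for 1 (33 and 1 over the list alone, adjusted p = 0.000136). IFN-γ-induced GTPases were higher for 23 of 33 with 0 lower (29 and 2 over the list alone, adjusted p = 4.1e-05). MHC class II was higher for 6 of 12 with 0 lower (7 over the list alone, adjusted p = 3.4e-06), with H2-Aa at 1.84 ± 0.13. Cholesterol synthesis was higher for 2 of 23 with 0 lower (7 over the list alone, adjusted p = 0.000282). MHC class I did not pass as a list (8 higher, 1 lower, 11 and 3 over the list alone, adjusted p = 0.0545). It passed in fry without the library that stood apart, with scaling and dispersions of the full fit kept (adjusted p = 0.0479). Macrophage markers were lower for 2 of 22 with 0 higher (3 over the list alone, adjusted p = 0.0181, adjusted p = 0.214 with an estimated correlation) and dendritic cell markers for 2 of 8 with 0 higher (2 over the list alone, adjusted p = 0.0104, adjusted p = 0.277 with an estimated correlation). The 581 calls were 291, 294 and 219 without the 0, 1.5 and 3 h libraries.

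**Figure D3:**
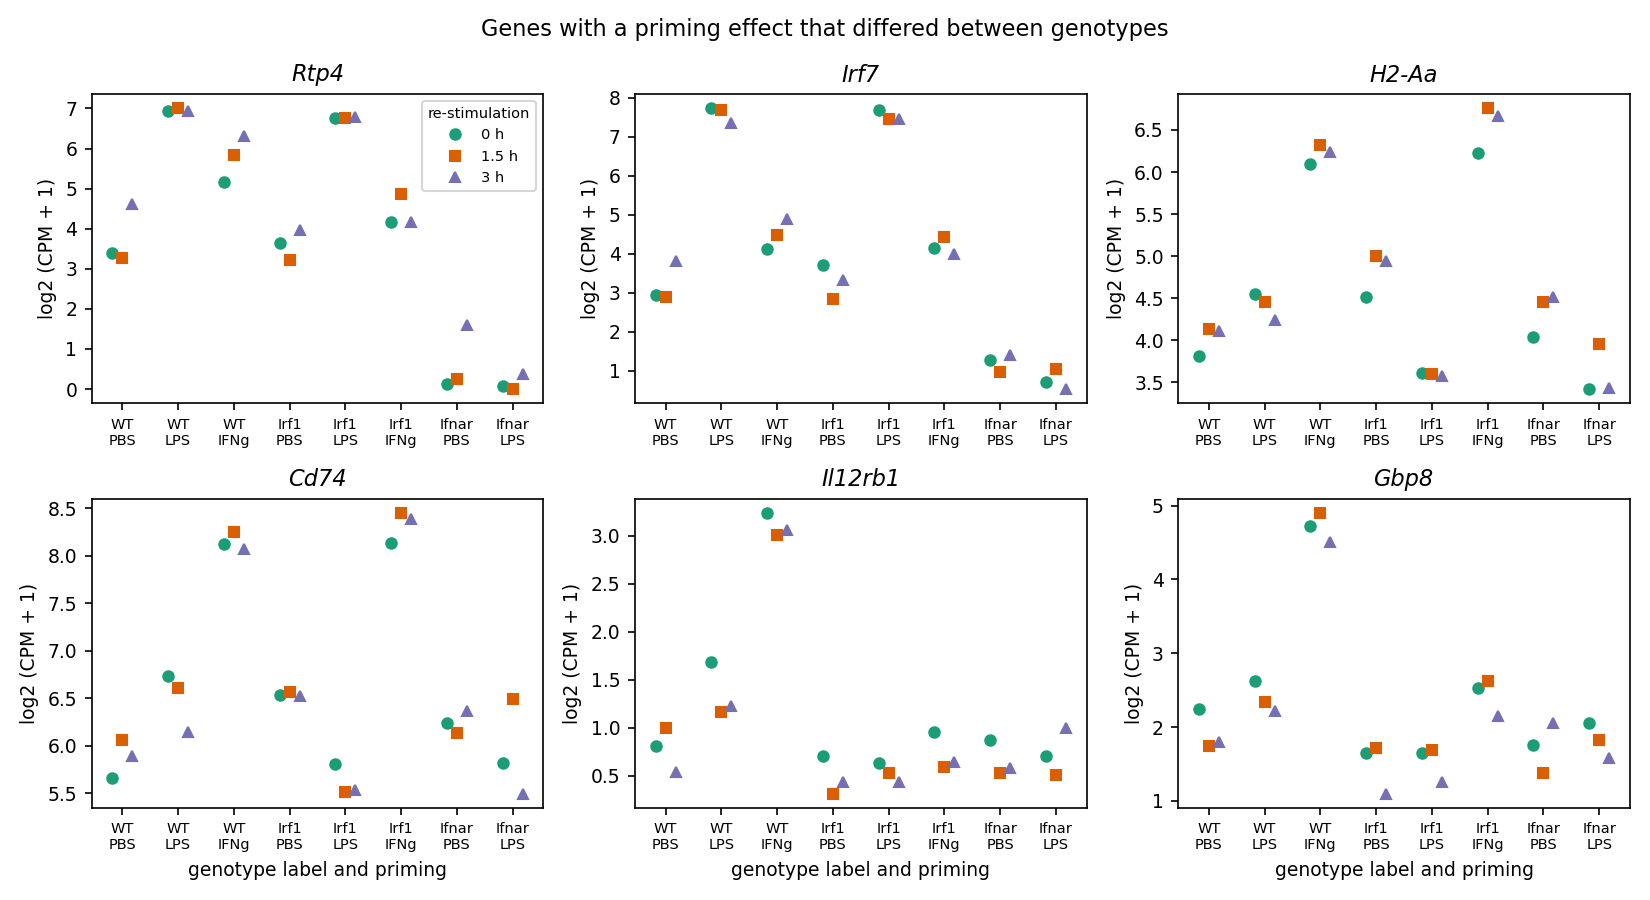
Rtp4, Irf7, H2-Aa, Cd74, Il12rb1 and Gbp8, whose priming effect differed between genotype labels, as log2 (CPM + 1). Each point is 1 library.

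In libraries labelled Irf1-/-, IFN-γ priming raised 324 genes and lowered 112 (n = 3 libraries per group), again led by interferon effectors. Cxcl9 rose by 8.27 ± 0.44 (adjusted p = 2.8e-10), from 0.083 to 27.3 CPM, Zbp1 by 6.94 ± 0.52, Iigp1 by 6.46 ± 0.60 and Tgtp2 by 6.33 ± 0.52. Serpina3f, a serine protease inhibitor, had 902 counts against 1, a ratio of 925 (95% counting interval 166 to 36579). Gbp6 (4.39 ± 0.49), Ly6a (4.29 ± 0.25), Gvin3 (4.20 ± 0.39), Mb21d2 (3.35 ± 0.28) and Batf2 (3.23 ± 0.33) followed. Falls were led by Fads2, a fatty acid desaturase (-0.94 ± 0.10, adjusted p = 3.8e-06), the chemokine Ccl9 (-0.73 ± 0.10) and Dtx4 (-0.72 ± 0.09). MHC class II rose for 10 of 12 with 0 lower (11 over the list alone, adjusted p = 1.5e-07), including H2-Aa (1.77 ± 0.13), H2-Ab1 (1.97 ± 0.16) and the invariant chain Cd74 (1.80 ± 0.18). MHC class I rose for 13 of 22 with 0 lower (17 over the list alone, adjusted p = 1.1e-05). IFN-γ-induced GTPases rose for 26 of 33 with 0 lower (29 over the list alone, adjusted p = 1.6e-07) and type I interferon-stimulated genes for 12 of 40 with 0 lower (19 over the list alone, adjusted p = 0.00228). Cholesterol synthesis fell for 11 of 23 with 0 higher (18 over the list alone, adjusted p = 2.2e-06) and proliferation for 5 of 36 with 0 higher (25 over the list alone, adjusted p = 0.000848). Macrophage markers rose for 8 of 22 with 0 lower (9 and 3 over the list alone, adjusted p = 1.6e-05). Dendritic cell markers passed fry as a list with 0 of 8 genes called in edgeR (0 over the list alone, adjusted p = 0.00928, adjusted p = 0.301 with an estimated correlation). LPS-induced mediators had 0 rises and 0 falls among 33 (5 falls over the list alone, adjusted p = 0.358). The 436 calls were 252, 224 and 136 without the 0, 1.5 and 3 h libraries.

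LPS priming in libraries labelled Irf1-/- raised 1034 genes and lowered 707 (n = 3 libraries per group), with many of the interferon-stimulated genes raised in WT and falls of the class II genes H2-Eb1, H2-Aa and H2-Ab1. Ccl5 rose by 7.88 ± 1.09, Cxcl9 by 6.77 ± 0.48, Zbp1 by 6.46 ± 0.55, Ifi206 by 5.01 ± 0.46, and Oasl2 by 4.51 ± 0.26. Ifi209 rose by 4.36 ± 0.28, Irf7 by 4.34 ± 0.27 (adjusted p = 2.5e-09), Ifit3 by 3.91 ± 0.61 and the antiviral GTPase Mx1 by 3.59 ± 0.69. Falls were led by Ighm, the immunoglobulin µ constant region (-3.27 ± 0.26, adjusted p = 7.8e-08, 6.02 to 0.616 CPM). H2-Eb1 (-1.78 ± 0.17, adjusted p = 6.2e-07), H2-Aa (-1.31 ± 0.14, adjusted p = 2.5e-06) and H2-Ab1 (-1.02 ± 0.17), neighbouring class II genes on chromosome 17 (34257689 to 34316674), fell together. As a list MHC class II split, with 3 of 12 higher and 5 lower (3 and 5 over the list alone, adjusted p = 0.220, median 0.15, mean -0.29). Fads2 (-1.24 ± 0.10) and Scd2 (-1.23 ± 0.15), desaturases of fatty acids, also fell. Type I interferon-stimulated genes rose for all 40 (40 over the list alone, adjusted p = 3.7e-07), MHC class I for 17 of 22 (17 over the list alone, adjusted p = 8.0e-07), both with 0 lower. GTPases rose for 22 of 33 with 1 lower (24 and 1 over the list alone, adjusted p = 2.1e-05). Cholesterol synthesis fell for 20 of 23 and proliferation for 25 of 36, with 0 higher in either (23 and 29 over the list alone, adjusted p = 1.0e-08 and 3.7e-05). Macrophage markers rose for 12 of 22 and fell for 1 (15 and 2 over the list alone, adjusted p = 2.9e-07). Dendritic cell markers rose for 2 of 8 and fell for 1 (2 and 1 over the list alone, adjusted p = 0.004, adjusted p = 0.393 with an estimated correlation) and neutrophil markers rose for 2 of 13 with 0 lower (3 over the list alone, adjusted p = 0.0241, adjusted p = 0.406 with an estimated correlation). The 1741 calls were 997, 1034 and 536 without the 0, 1.5 and 3 h libraries and 2784 when only the compared libraries were fitted.

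Genotype labels were then compared at equal priming. Between PBS-primed libraries labelled Irf1-/- and WT 105 genes differed, 42 higher and 63 lower, and after LPS priming 220, 86 higher and 134 lower (n = 3 libraries per group). The difference was largest after IFN-γ priming, with 379 genes higher and 440 lower. Some genes separated the labels throughout. Rpl31-ps8, a processed pseudogene, was higher (3.28 ± 0.19 after PBS, 3.16 ± 0.19 after LPS, 2.92 ± 0.19 after IFN-γ). So were Rab4a, a GTPase of recycling endosomes (1.87 ± 0.17, 1.91 ± 0.17, 1.78 ± 0.18), and, after PBS and LPS, the protease Plau (1.01 ± 0.10 and 1.19 ± 0.10). Il18bp, the soluble IL-18 inhibitor, was lower (-1.71 ± 0.16, -2.86 ± 0.15, -3.43 ± 0.15, adjusted p = 4.0e-06, 3.3e-10 and 1.3e-11). The long noncoding RNA AW112010 (chromosome 19, 11047612 to 11055808) was lower by -3.40 ± 0.49, -3.40 ± 0.42 and -6.26 ± 0.47.

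Within IFN-γ-primed cells the libraries labelled Irf1-/- had lower levels of some genes that IFN-γ raised in WT and higher levels of other genes. Lower were Gbp4 (-4.37 ± 0.38, adjusted p = 1.9e-07), Flt1, a VEGF receptor (-4.08 ± 0.34), Il12rb1 (-3.52 ± 0.26, adjusted p = 3.8e-08, 0.667 against 7.59 CPM), Clic5, a chloride channel protein (-3.16 ± 0.25), and Iigp1 (-3.12 ± 0.31). Nos2, inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), stood at 0.101 against 17.3 CPM (-6.99 ± 0.78, adjusted p = 5.6e-06), a call that was lost without the 3 h libraries. Among list members, Casp12 (-4.73 ± 0.52), Casp1 (-1.39 ± 0.10), Oas3 (-1.86 ± 0.09), the tapasin genes Tapbp (-1.25 ± 0.10) and Tapbpl (-2.25 ± 0.18), the immunoproteasome subunit Psmb10 (-2.23 ± 0.20) and the cytokine Il27 (-2.86 ± 0.43) were lower. Higher were Serpina3f (3.00 ± 0.29), Adamts1, a matrix protease (2.17 ± 0.27), Cxcl9 (2.10 ± 0.24, adjusted p = 9.2e-06, 27.3 against 6.41 CPM), Atp6v0d2, a proton pump subunit (1.98 ± 0.07, adjusted p = 5.1e-13), Serpinb1a (1.81 ± 0.17) and Itgb3 (1.52 ± 0.09).

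MHC class I was lower for 15 of 22 with 0 higher in IFN-γ-primed libraries labelled Irf1-/- (18 over the list alone, adjusted p = 4.6e-06), and for 6 of 22 with 0 higher after LPS (13 over the list alone, adjusted p = 0.00324). Cell death genes were lower for 12 of 33 with 0 higher after IFN-γ (14 and 1 over the list alone, adjusted p = 3.8e-05) and for 4 after LPS (9 over the list alone, adjusted p = 0.00499). GTPases and effectors were lower for 4, 11 and 18 of 33 and higher for 0, 1 and 3 after PBS, LPS and IFN-γ (16, 16 and 21 lower over the list alone, adjusted p = 0.00873, 0.00234 and 0.000346). MHC class II was lower for 5 of 12 with 0 higher after LPS (7 over the list alone, adjusted p = 0.000151), including H2-DMa (-1.21 ± 0.13) and H2-Aa (-0.89 ± 0.14), and not after IFN-γ (1 higher, 2 lower, 4 and 2 over the list alone, adjusted p = 0.576). Type I interferon-stimulated genes did not pass as a list after LPS (0 higher, 5 lower, 5 over the list alone, adjusted p = 0.307). They were lower for 10 of 40 and higher for 1 after IFN-γ (17 and 2 over the list alone, adjusted p = 0.0335, adjusted p = 0.313 with an estimated correlation). Glycolysis genes were lower for 6 of 23 with 0 higher after IFN-γ (7 over the list alone, adjusted p = 0.000230, adjusted p = 0.0518 with an estimated correlation). Alternative activation genes were higher for 1, 3 and 7 of 19 and lower for 0, 1 and 1 after PBS, LPS and IFN-γ (3, 7 and 9 higher over the list alone, adjusted p = 0.00185, 0.000164 and 0.000146). Dendritic cell markers were higher for 1 of 8 with 0 lower after IFN-γ (1 over the list alone, adjusted p = 0.0323, adjusted p = 0.393 with an estimated correlation). The elastase Mmp12 stood at 0.58 ± 0.07 after LPS and 0.79 ± 0.07 after IFN-γ. Genes flanking Irf1 passed fry after LPS (adjusted p = 0.0468, adjusted p = 0.303 with an estimated correlation) and after IFN-γ (adjusted p = 0.0438, adjusted p = 0.403 with an estimated correlation). edgeR called 0 of these 14 genes in either (1 and 0 over the list alone). Within WT this list passed fry too, so its calls are not particular to the label. It did so for LPS priming (adjusted p = 0.0241, adjusted p = 0.422 with an estimated correlation) and for IFN-γ against LPS (adjusted p = 0.0493, adjusted p = 0.402 with an estimated correlation). Without the 0, 1.5 and 3 h libraries the counts were 49, 98 and 15 after PBS, 86, 135 and 56 after LPS and 546, 549 and 240 after IFN-γ. With only the compared libraries fitted they were 60, 423 and 1414.

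Whether the priming effect itself differs by label is asked by the contrast of 4 groups. For IFN-γ priming it gave 48 genes, 32 with a larger and 16 with a smaller effect in WT (n = 3 libraries in each of 4 groups). Atp6v0d2 held in every alternative (-1.39 ± 0.10, adjusted p = 1.3e-07): it rose by 1.51 with the Irf1-/- label (adjusted p = 2.4e-11), while its 0.12 in WT did not pass (adjusted p = 0.411). Oas3 (1.16 ± 0.13) and Tgm2, transglutaminase 2 (1.13 ± 0.13), had larger effects in WT in every alternative as well (adjusted p = 0.000195 for both). Clic5 (2.81 ± 0.37, adjusted p = 0.000688), Il12rb1 (2.66 ± 0.48, adjusted p = 0.0167), Flt1 (2.39 ± 0.49, adjusted p = 0.0405) and Gbp8 (1.88 ± 0.32, adjusted p = 0.0144) had larger rises in WT. MHC class I genes had larger effects in WT for 6 of 22 with 0 smaller (13 over the list alone, adjusted p = 0.00172). Cell death genes did for 1 of 33 (5 over the list alone, adjusted p = 0.0380, adjusted p = 0.0614 with an estimated correlation) and glycolysis genes for 2 of 23 (4 over the list alone, adjusted p = 0.00737). GTPases as a list did not differ (3 larger, 0 smaller, 3 and 1 over the list alone, adjusted p = 0.625), nor did type I interferon-stimulated genes (1 larger, 0 smaller, 1 over the list alone, adjusted p = 0.352). Leaving out the 0, 1.5 or 3 h libraries left 8, 11 and 5 genes: without 0 h Il12rb1, Flt1 and Gbp8 no longer passed, without 1.5 h Clic5, Il12rb1 and Gbp8, and without 3 h all 4.

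To compare sizes without choosing and measuring genes on the same libraries, genes were called in WT on 2 times and read at the third. At the left-out 0, 1.5 and 3 h, genes raised by IFN-γ had median priming effects of 0.68, 0.75 and 0.97 in WT and 0.33, 0.44 and 0.45 in the libraries labelled Irf1-/-. The effect was smaller with that label for 75.4%, 73.1% and 82.0% of 289, 297 and 194 genes. Genes raised by LPS had medians of 0.60, 0.48 and 0.63 in WT, 0.53, 0.48 and 0.63 with the Irf1-/- label and 0.16, 0.31 and 0.10 with the Ifnar-/- label (605, 849 and 449 genes). Genes lowered by LPS (371, 615 and 210) had medians of -0.39, -0.40 and -0.42 in WT, -0.31, -0.36 and -0.37 with the Irf1-/- label and -0.03, -0.41 and -0.07 with the Ifnar-/- label. At 1.5 h the fall was smaller in Ifnar-/- for 48.6% of them, and at 0 and 3 h for 87.6% and 91.4%. With genes called at adjusted p under 0.01 the 1.5 h value turned to 62.7% (209 genes, -0.53 in WT and -0.41 in Ifnar-/-). Genes raised by LPS in WT had the same sign in Ifnar-/- libraries for 75.4%, 79.0% and 62.4%. Genes lowered by IFN-γ (70, 115 and 39) had medians of -0.48, -0.45 and -0.45 in WT and -0.18, -0.33 and -0.27 with the Irf1-/- label. The Ifnar-/- values at 1.5 h rest on the library that stood apart. Reading WT at a time whose genes were called in WT favours WT, and no p-value is given for these medians.

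**Figure D4:**
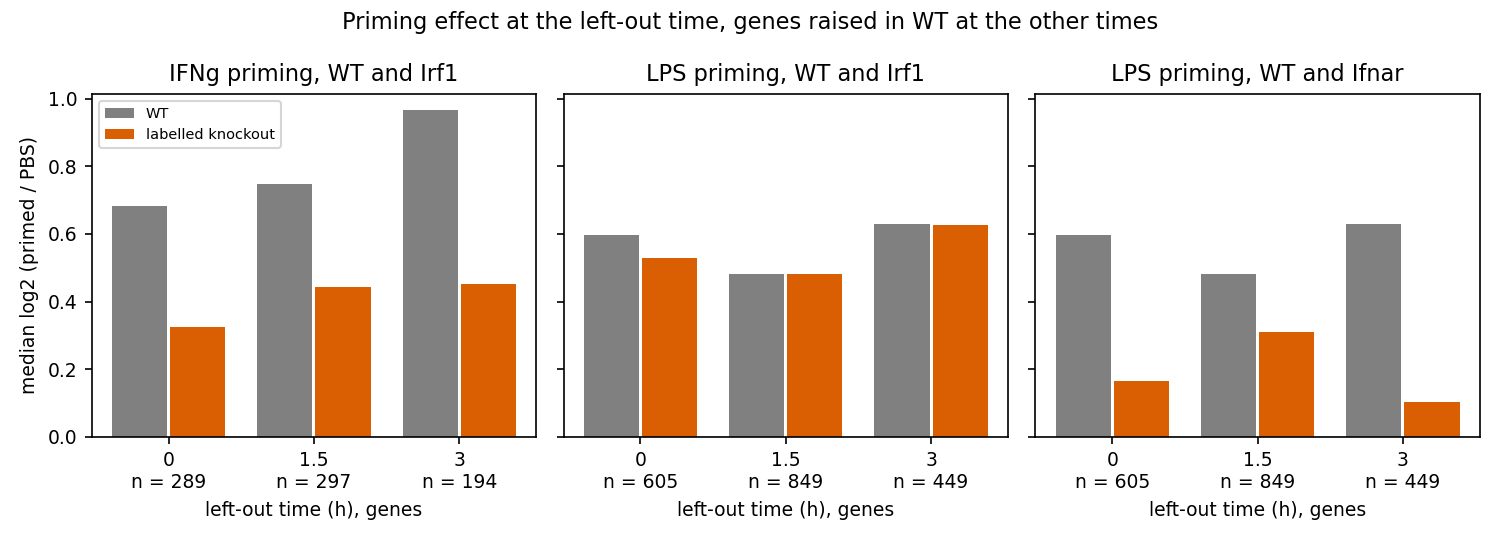
Median priming effect of genes called higher in WT on 2 times, read at the left-out time, in WT and in each knockout label.

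For LPS priming the same contrast between WT and the Irf1-/- label gave only 4 genes, 3 of them MHC class II. H2-Aa (1.74 ± 0.20, adjusted p = 0.000462), H2-Ab1 (1.72 ± 0.24, adjusted p = 0.00500) and Cd74 (1.57 ± 0.25, adjusted p = 0.0158) had larger effects in WT. H2-Aa rose by 0.44 in WT (adjusted p = 0.0402) and fell with the label, from 15.3 to 20.4 CPM in WT and from 27.6 to 11.03 CPM with the label. The rise in WT alone was no longer called without any 1 of the 3 times. Cd5l, a secreted scavenger receptor protein of macrophages, had a smaller effect in WT (-0.89 ± 0.14, adjusted p = 0.0139). MHC class II differed as a list, with 3 of 12 larger and 0 smaller (5 over the list alone, adjusted p = 0.000577). Type I interferon-stimulated genes did not (0 of 40 in edgeR, 1 over the list alone, adjusted p = 0.883). The calls were 2, 0 and 0 without the 0, 1.5 and 3 h libraries: without 0 h Cd74 and Cd5l no longer passed, and without 1.5 h or 3 h none of the 4 did. At unadjusted p under 0.05 there were 289 genes in the full fit.

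In Ifnar-/- libraries LPS priming raised 177 genes and lowered 65 (n = 3 libraries per group, with the library that stood apart among them). Rises were led by Slpi (3.02 ± 0.20, adjusted p = 2.9e-08), Cd55 (2.26 ± 0.35), Marco, a scavenger receptor (1.92 ± 0.20, adjusted p = 3.3e-05), Gsta3, a glutathione transferase (1.63 ± 0.15), Slc39a4, a zinc importer (1.57 ± 0.20), and Ass1, argininosuccinate synthase (1.49 ± 0.07, adjusted p = 3.6e-10). Tox2 fell (-1.11 ± 0.16). So did H2-Eb1 (-1.33 ± 0.17) and H2-Aa (-0.78 ± 0.14), both no longer called without the 3 h libraries. Of 40 type I interferon-stimulated genes 0 rose and 1 fell (0 and 1 over the list alone, adjusted p = 0.925) and of 33 GTPases 0 rose and 1 fell (0 and 2 over the list alone, adjusted p = 0.911). Of 22 MHC class I genes 0 changed in edgeR (0 over the list alone, adjusted p = 0.699) and of 12 MHC class II genes 1 rose and 3 fell (1 and 4 over the list alone, adjusted p = 0.154). Other lists moved in the same direction as in WT: cholesterol synthesis fell for 3 of 23 with 0 higher (12 over the list alone, adjusted p = 0.000164). Macrophage markers rose for 4 of 22 with 0 lower (5 over the list alone, adjusted p = 0.000199) and antimicrobial effectors for 5 of 22 with 0 lower (7 and 2 over the list alone, adjusted p = 0.00441). Glycolysis genes passed fry with 0 of 23 genes called (4 over the list alone, adjusted p = 0.0452, adjusted p = 0.312 with an estimated correlation). The 242 calls were 427, 120 and 32 without the 0, 1.5 and 3 h libraries, 415 with DESeq2, and 0 in edgeR with only the compared libraries fitted, where none of the named genes passed. Without the LPS-primed 1.5 h library 177 genes were called, 125 of them shared.

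Against WT, PBS-primed Ifnar-/- libraries had lower interferon-stimulated transcripts over the 3 times, 2 of which follow re-stimulation (115 genes higher, 110 lower, n = 3 libraries per group). Lower were Oas1a (-8.24 ± 0.31, adjusted p = 1.4e-12), Oas2 (-6.63 ± 0.42) and Oas3 (-3.34 ± 0.12, adjusted p = 1.1e-12), oligoadenylate synthases on chromosome 5 (120730333 to 120907521). So were Rtp4 (-4.14 ± 0.52), Oasl2 (-3.81 ± 0.34), Ifi27l2a (-2.72 ± 0.23), Irf7 (-2.69 ± 0.36) and Ifnar1 itself (-1.59 ± 0.09, adjusted p = 5.3e-10). Adam33, a metalloprotease (-2.24 ± 0.19), was lower too. Higher were Itpa-ps1, a processed pseudogene (5.80 ± 0.23, adjusted p = 1.7e-12), Eif3j2, a translation initiation factor copy (3.67 ± 0.24), Tnfsf13os, an antisense transcript (2.01 ± 0.17), and Fah, of tyrosine breakdown (1.73 ± 0.14). Type I interferon-stimulated genes were lower for 20 of 40 with 0 higher (32 over the list alone, adjusted p = 2.5e-05), and interferon receptors and transcription factors for 5 of 32 with 0 higher (6 over the list alone, adjusted p = 0.000137). MHC class I was lower for 3 of 22 with 0 higher (7 over the list alone, adjusted p = 0.0386, adjusted p = 0.290 with an estimated correlation). Neutrophil markers were higher for 2 of 13 with 0 lower (2 over the list alone, adjusted p = 0.0418, adjusted p = 0.238 with an estimated correlation). Genes flanking Ifnar1 were higher for 1 and lower for 1 of 18 (1 and 1 over the list alone, adjusted p = 0.00280, adjusted p = 0.0816 with an estimated correlation). The 225 calls were 160, 1727 and 77 without the 0, 1.5 and 3 h libraries and 323 without the LPS-primed Ifnar-/- library at 1.5 h alone, with 345 in DESeq2 and 95 with only the compared libraries fitted.

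After LPS priming 715 genes were higher and 860 lower in Ifnar-/- libraries than in WT (n = 3 libraries per group). Without the 1.5 h libraries fewer genes differed after LPS than after PBS priming (1017 against 1727), so the 2 totals are not ranked here. Oas1g had 0 counts in Ifnar-/- libraries against 1982 in WT, at least 645-fold lower, Ifi44 0 against 853, at least 278-fold, and Ifi213 0 against 533, at least 174-fold. Oas2 had 2 against 4032 counts, a ratio of 1969 (95% counting interval 545 to 16265). Irf7 (-8.09 ± 0.37), Usp18, the deISGylase that restrains interferon signalling (-7.97 ± 0.52), Zbp1 (-7.02 ± 0.39) and Irf9 (-2.94 ± 0.10) were lower. Ighm was higher (5.12 ± 0.29, adjusted p = 2.0e-10, 9.87 against 0.279 CPM), as were Ttc3, a ubiquitin ligase gene near Ifnar1 on chromosome 16 (1.78 ± 0.11), and Fah (2.44 ± 0.14). All 40 type I interferon-stimulated genes and all 22 MHC class I genes were lower (40 and 22 over the list alone, adjusted p = 1.0e-08 and 2.6e-08). So were GTPases for 26 of 33 (29 over the list alone, adjusted p = 1.3e-06) and interferon receptors and transcription factors for 15 of 32 (18 over the list alone, adjusted p = 2.6e-08), all with 0 higher. Cholesterol synthesis was higher for 13 of 23 with 0 lower (15 over the list alone, adjusted p = 2.6e-06). Several calls did not hold under camera. For MHC class II these were 5 of 12 lower and 0 higher (9 and 1 over the list alone, adjusted p = 0.000274, adjusted p = 0.113 with an estimated correlation) and for cell death 10 of 33 lower and 1 higher (11 and 2 over the list alone, adjusted p = 0.000151, adjusted p = 0.0706 with an estimated correlation). Proliferation had 10 of 36 higher and 0 lower (17 over the list alone, adjusted p = 0.000671, adjusted p = 0.160 with an estimated correlation). TLR4 components had 5 of 34 lower and 0 higher (7 over the list alone, adjusted p = 0.0425, adjusted p = 0.525 with an estimated correlation). Macrophage markers were lower for 6 of 22 and higher for 3 (6 and 3 over the list alone, adjusted p = 0.000594, adjusted p = 0.188 with an estimated correlation). Dendritic cell markers were lower for 2 of 8 with 0 higher (2 over the list alone, adjusted p = 0.00737, adjusted p = 0.497 with an estimated correlation). Mitochondrially encoded transcripts were higher for 4 of 13 with 0 lower (6 over the list alone, adjusted p = 0.0123, adjusted p = 0.320 with an estimated correlation). Heat shock genes were lower for 7 of 29 and higher for 1 (8 and 1 over the list alone, adjusted p = 0.000977, adjusted p = 0.227 with an estimated correlation). Alternative activation was higher for 4 of 19 with 0 lower (6 and 1 over the list alone, adjusted p = 0.000129, adjusted p = 0.0603 with an estimated correlation). Antimicrobial effectors were lower for 7 of 22 and higher for 3 (11 and 3 over the list alone, adjusted p = 0.0438, adjusted p = 0.527 with an estimated correlation). Genes flanking Ifnar1 were lower for 3 of 18 and higher for 2 (6 and 2 over the list alone, adjusted p = 0.00207, adjusted p = 0.312 with an estimated correlation) and genes flanking Irf1 higher for 1 of 14 with 0 lower (3 over the list alone, adjusted p = 0.0329, adjusted p = 0.477 with an estimated correlation). Negative regulators of LPS signalling had their lowest adjusted p here, 0.107, and were called in 0 of 14 comparisons by fry. The 1575 calls were 880, 1017 and 499 without the 0, 1.5 and 3 h libraries, 898 with only the compared libraries fitted and 1537 without the LPS-primed 1.5 h library.

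The LPS priming effect differed between WT and Ifnar-/- for 209 genes, 144 larger and 65 smaller in WT (n = 3 libraries in each of 4 groups). Irf7 (5.40 ± 0.61, adjusted p = 2.9e-05), Ifi209 (4.71 ± 0.57, adjusted p = 7.0e-05), Oasl2 (3.70 ± 0.57) and Oas3 (2.80 ± 0.18, adjusted p = 3.9e-08) rose more in WT in every alternative. Ighm fell more in WT (-3.63 ± 0.38, adjusted p = 1.4e-05), where it went from 3.01 to 0.279 CPM against 8.39 to 9.87 CPM in Ifnar-/-, and so did Itgb3 (-1.47 ± 0.12, adjusted p = 9.5e-07) and Fads2 (-0.94 ± 0.14). Larger effects in WT were found for 23 of 40 type I interferon-stimulated genes (32 over the list alone, adjusted p = 6.6e-05) and 15 of 22 MHC class I genes (22 over the list alone, adjusted p = 9.6e-06). The same held for 8 of 33 GTPases (20 over the list alone, adjusted p = 0.000585) and 4 of 12 MHC class II genes (8 over the list alone, adjusted p = 0.000346). None of these 4 lists had a smaller effect in WT for any gene. Cell type markers moved along: macrophage markers had larger effects in WT for 2 of 22 and smaller for 1 (4 and 2 over the list alone, adjusted p = 0.0156, adjusted p = 0.118 with an estimated correlation), and dendritic cell markers larger for 1 of 8 and smaller for 0 (1 over the list alone, adjusted p = 0.00873, adjusted p = 0.171 with an estimated correlation). The fall of cholesterol synthesis was larger in WT for 5 of 23 with 0 smaller (14 over the list alone, adjusted p = 3.0e-05). The calls were 70 and 61 without the 0 and 3 h libraries, 421 without the LPS-primed Ifnar-/- library at 1.5 h, 327 with DESeq2 and 77 with only the compared libraries fitted.

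Re-stimulation with low-dose LPS raised 605 genes and lowered 340 in PBS-primed WT (n = 1 library at 0 h and 2 after re-stimulation). The design fits each 0 h library exactly, so the spread comes only from 1.5 h against 3 h over the 8 groups and is assumed, not measured, for 0 h. A deviation of a single 0 h library can thus be called as a response. The largest rises were the cytokine Il1b (7.79 ± 0.62, adjusted p = 9.1e-06), the neutrophil chemokines Cxcl1 (7.38 ± 0.88) and Cxcl2 (6.32 ± 0.51), Gem, a small GTPase (6.77 ± 0.60), Cxcl10, an interferon-induced chemokine (6.69 ± 0.62), and Cd69, an early activation antigen (5.38 ± 0.24, adjusted p = 2.1e-07). Falls were led by Dusp6, an ERK phosphatase (-2.67 ± 0.21, adjusted p = 8.8e-06), Rgs2 (-1.73 ± 0.27), Lpar6 (-1.52 ± 0.13) and Thbd, thrombomodulin (-1.51 ± 0.20). Without the LPS-primed Ifnar-/- library at 1.5 h the 945 calls became 1686, with only WT libraries fitted 2452 and without a term for the 1.5-to-3 h shift 147.

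Differences between responses rest on 1 library at 0 h in each of 2 groups, with the same limit. In WT 7 genes were called with a smaller response after LPS than after PBS priming, among them Acod1, the enzyme making itaconate (-3.30 ± 0.43), Cd69 (-2.36 ± 0.30) and Ccrl2, a chemokine-binding receptor (-1.80 ± 0.24), each at adjusted p = 0.0216. Another was Tnip3, an NF-κB inhibitor (-1.71 ± 0.25, adjusted p = 0.0415). With the Irf1-/- label there were 2, Ccrl2 (-2.26 ± 0.24, adjusted p = 0.00987) and the adhesion molecule Icam1 (-1.41 ± 0.17, adjusted p = 0.0157). In Ifnar-/- libraries there were 35, including Acod1 (-3.64 ± 0.46, adjusted p = 0.00932), Nfkbiz, an IκB family regulator (-3.51 ± 0.42, adjusted p = 0.00655), the cytokine Il1a (-3.50 ± 0.53, adjusted p = 0.0232) and Gpr85 (-2.48 ± 0.45, adjusted p = 0.0469). With only Ifnar-/- libraries fitted 43 were called, of which only 10 were among the 35. After IFN-γ priming edgeR called 0 response differences in WT (236 genes at unadjusted p under 0.05, 1 in DESeq2) and 0 with the Irf1-/- label (460 at unadjusted p under 0.05, 8 in DESeq2). Over 335 genes induced at least 2-fold in PBS-primed WT, the median response was 1.72 in those cells, 0.97 after LPS and 1.48 after IFN-γ priming. With the Irf1-/- label it was 1.70, 1.02 and 1.19 and in Ifnar-/- libraries 1.69 after PBS and 0.74 after LPS priming, or 0.80 without the library that stood apart. Those are fitted values over 1.5 and 3 h, and the next ones are plain log2 ratios of CPM + 2 to the group's 0 h library. On this other measure the median was 0.293 in the library that stood apart and 0.800 in the LPS-primed Ifnar-/- library at 3 h. At 1.5 h after LPS priming it was 0.591 in WT and 0.565 with the Irf1-/- label. These medians rest on 1 library at 0 h per group and carry no test. Choosing genes by their response in PBS-primed WT favours that group, while the other PBS-primed groups were not used in the choice and reached 1.70 and 1.69. Without the LPS-primed Ifnar-/- library at 1.5 h the 7, 2 and 35 calls became 26, 24 and 47, the last from 1 library at 3 h against 1 at 0 h after LPS priming, and without a term for the 1.5-to-3 h shift 0, 1 and 1, where only Ccrl2 with the Irf1-/- label still passed among the genes named here.

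**Figure D5:**
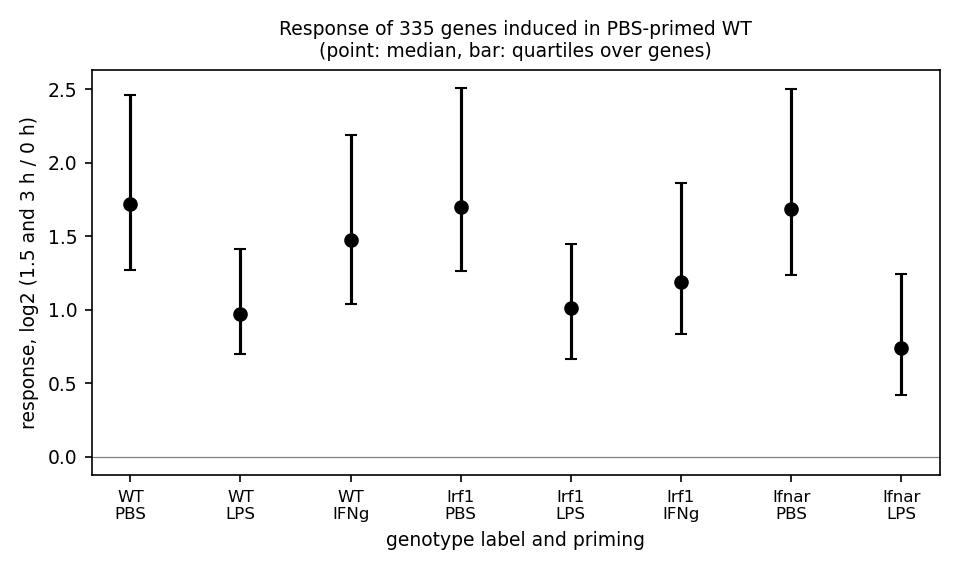
Response to re-stimulation of 335 genes induced in PBS-primed WT, as median and quartiles over genes in each of the 8 groups.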

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

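In this part, the tests of depth, of single wrong labels, of a remaining Irf1 transcript and of the chromosome segments around Irf1 and Ifnar1, and the fits without the LPS-primed Ifnar-/- library at 1.5 h or with gene length trends removed, were chosen only after the result was seen.

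The results listed here stand out because a priming effect or a response differed between 2 groups in a direct test of that difference (edgeR's quasi-likelihood F test, Benjamini-Hochberg adjusted). The IFN-γ priming effect differed between WT and the Irf1-/- label for 48 genes. Larger in WT were Clic5 (2.81), Il12rb1 (2.66), Flt1 (2.39) and Gbp8 (1.88), and smaller in WT were Atp6v0d2 (-1.39), Mreg, of melanosome transport (-1.27), Gpr34, a lysophospholipid receptor (-1.17), and Enc1, an actin-binding protein (-1.15). The LPS priming effect differed between the same labels for 4 genes, H2-Aa (1.74), H2-Ab1 (1.72), Cd74 (1.57) and Cd5l (-0.89). Between WT and Ifnar-/- it differed for 209 genes, including Rtp4 (5.87), Oasl1 (5.79), Irf7 (5.40) and Ifi209 (4.71) on the side of WT and Ighm (-3.63), Itgb3 (-1.47), Acy1, an aminoacylase (-1.14), and Fbln5 (-1.12) on the other. Rtp4 and Oasl1 no longer passed without the 0 h or 3 h libraries, and Oasl1 also not without 1.5 h. Mreg, Gpr34, Enc1 and Acy1 no longer passed without any 1 of the 3 times, and Fbln5 without 0 h or 3 h.

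The response to re-stimulation, which rests on 1 library at 0 h per group without a measured spread, was called smaller after LPS than after PBS priming for 7 genes in WT, including Acod1 (-3.30), Cd69 (-2.36), Ccrl2 (-1.80) and Tnip3 (-1.71). With the Irf1-/- label the count was 2, Ccrl2 (-2.26) and Icam1 (-1.41). In Ifnar-/- libraries it was 35, including Acod1 (-3.64), Nfkbiz (-3.51), Il1a (-3.50) and Gpr85 (-2.48). The last group includes the library that stood apart. Without it 47 genes were called, from 1 library at 3 h against 1 at 0 h after LPS priming, which is no independent check of the 35. Without a term for the 1.5-to-3 h shift the 3 counts were 0 (edgeR, 45 in DESeq2 with the term), 1 and 1.

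Other splits of the same libraries were counted for each comparison. For the 3 differences between genotype labels, 8, 5 and 8 of 32 splits gave as many genes as the real 48, 4 and 209, so chance is not excluded by this count, with highest other values of 927, 420 and 1979. These high counts arise when only PBS-primed libraries trade genotype labels, which turns the difference into the sum of the genotype differences after PBS and after priming, a structure of the samples. When whole times trade labels, in 4 splits, the highest other value was 0 for each of the 3. Such trades move the genotype differences into the error, and 4 splits are too few for a share under 0.05, so this count decides nothing. For the 11 comparisons of 2 groups the 10 splits are too few for a share under 0.05. Only the real split reached the real count (1 of 10) for IFN-γ priming in WT (652) and with the Irf1-/- label (436), LPS priming in both (1908 and 1741), IFN-γ against LPS in WT (581), the Irf1-/- label against WT after PBS, LPS and IFN-γ (105, 220 and 819) and Ifnar-/- against WT after PBS and LPS (225 and 1575), with a highest other value of 0, and of 1 for the 819. For LPS priming in Ifnar-/- libraries (242) 2 of 10 reached it, with 1439 in the split that exchanges the 1.5 h libraries.

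The first pattern weighed is the LPS-primed Ifnar-/- library at 1.5 h, which lies among unstimulated libraries. A gene length trend argues poorly for it, since with length trends removed the spread of its residuals stayed at 0.308, above the highest other value of 0.259. For a library without any re-stimulation, the median log2 ratio to the 0 h library of its group was read over 335 induced genes. It was 0.293, above the 0.0896 seen between 0 h libraries of LPS priming. That median was taken with the length trend of this library left in, which may itself shift these genes, so it does not decide the question. A low depth is argued against by its 20.06 M counts, against a lowest total of 19.66 M elsewhere. Other measures of the same library were extreme: the lowest mitochondrial share (1.18%), the highest share of the 10 most abundant genes (17.8%) and the lowest normalisation factor (0.945). An absent, weak or late re-stimulation, a wrong label from outside the series and a real difference of these cells stay open, and with 1 library they cannot be separated.

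The second pattern is that Irf1 mRNA is kept in libraries labelled Irf1-/-. Wrong labels of single libraries are argued against by Rpl31-ps8, the largest rise with the label after PBS and also after LPS. Read only in libraries of a priming on which it was not chosen, it lies above the others in 9 of the 9 so labelled (15.0 to 20.2 CPM against 1.63 to 3.13 CPM). An allele whose transcript still gives counts stays open. Irf1 was induced at 1.5 h by 5.42-, 2.18- and 2.03-fold with the label after PBS, LPS and IFN-γ and by 9.22-, 3.06- and 4.35-fold in WT. Wild-type cells under a wrong label would be induced as well, so these folds decide nothing. Such an allele may lack part of the coding sequence, which gene counts cannot show. Wild-type cells of the same background in all 9 libraries are argued against by the genes that differed under all 3 primings. Of these, 8.22% lay within 10 Mb of Irf1, against 1.37% of other tested genes (two-sided Fisher's exact p = 0.000565). Without genes called for either priming in WT it was 12.5% against 1.32% (two-sided Fisher's exact p = 0.00395). Another wrong genotype for the whole set, or wild-type cells of another background, stays open. The lower Il18bp and Gbp4 with this label after IFN-γ priming were not tested apart from culture.

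The third pattern is the set of 74 genes that differ between the Irf1-/- label and WT under all 3 primings. A chromosome segment carried along with the targeted gene goes with part of it: 8.22% of those with a position (6 of 73) lie within 10 Mb of Irf1, against 1.37% of other tested genes (odds ratio 6.43, 95% interval 2.25 to 15.0, two-sided Fisher's exact p = 0.000565). For Ifnar-/- the same count gave 5.17% against 0.481% (9 genes, odds ratio 11.3, interval 4.85 to 23.3, two-sided Fisher's exact p = 3.9e-07). These counts hold likely targets of the pathways, Ifi47 and Gm12250 near Irf1 and Mx1 and Mx2 near Ifnar1. Without genes called for either priming in WT, 3 of 24 lay near Irf1 (12.5% against 1.32%, odds ratio 10.6, interval 2.01 to 36.2, two-sided Fisher's exact p = 0.00395) and 7 of 100 near Ifnar1 (7% against 0.539%, odds ratio 13.9, interval 5.22 to 31.5, two-sided Fisher's exact p = 2.0e-06). A gene length trend is argued against, since 97.3% of the 74 were still called with length trends removed. Most of the set lies outside this 10 Mb window. The count covers neither a longer segment nor effects of a segment on genes elsewhere. A segment, strain background, culture and loss of Irf1 function thus stay open for the rest.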

How the results depend on the processing

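In this part, the fits without the LPS-primed Ifnar-/- library at 1.5 h and those with gene length trends removed were chosen only after the result was seen. Over 784 pairs of a named gene and a comparison and 7735 alternative values, 0 changed direction. All of these pairs were called in the main fit. For the largest rises and falls the naming rule also asked for the same sign at every time compared. A reversal was thus hardly possible, so the 0 is no measure of robustness. No scaling moved the median of all genes by more than 0.1. DESeq2's size factors in place of TMM changed no count of genes by more than 1.5 times. For the changes below the cause was not tested. Some alternatives also have fewer libraries, and these gave fewer calls in some comparisons and more in others.

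Leaving out 1 time at once gave, lowest to highest, 233 to 412 genes for IFN-γ priming in WT, 659 to 1464 for LPS priming in WT, 136 to 252 and 536 to 1034 for the same with the Irf1-/- label and 32 to 427 for LPS priming in Ifnar-/-. For IFN-γ against LPS in WT it gave 219 to 294, for the Irf1-/- label against WT 15 to 98 after PBS, 56 to 135 after LPS and 240 to 549 after IFN-γ, and for Ifnar-/- against WT 77 to 1727 after PBS and 499 to 1017 after LPS. For the differences between WT and the Irf1-/- label it gave 5 to 11 (IFN-γ) and 0 to 2 (LPS), and for that between WT and Ifnar-/- 61 to 226. Where 1 time is left out each group keeps 2 libraries. This was not run for the responses, where no residual degrees of freedom would remain.

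With only the compared libraries fitted, counts were 1133 and 3380 for IFN-γ and LPS priming in WT, 2784 for LPS priming with the Irf1-/- label and 0 in edgeR for LPS priming in Ifnar-/-. Against WT they were 60, 423 and 1414 for the Irf1-/- label after PBS, LPS and IFN-γ, 95 and 898 for Ifnar-/- after PBS and LPS, and 77 for the LPS difference between WT and Ifnar-/-. With only the libraries of a genotype, the response in PBS-primed WT had 2452 genes, and response differences 75 (WT, LPS), 13 (Irf1-/- label, IFN-γ) and 94 (Irf1-/- label, LPS). The DESeq2 test gave 415 for LPS priming in Ifnar-/-, 168 and 345 for the Irf1-/- label and Ifnar-/- against PBS-primed WT, 96, 7 and 327 for the 3 differences, and for response differences 1 and 45 in WT (IFN-γ, LPS), 8 and 46 with the Irf1-/- label and 129 in Ifnar-/-. With only the Ifnar-/- libraries, 43 genes were called for the last, 10 of them among the 35. Without a filter on low counts the response differences were 1, 50, 4, 44 and 203 in the same order. A design with a response per group gave 28 and 2 for the IFN-γ and LPS differences between WT and the Irf1-/- label.

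Without a term for the shift from 1.5 to 3 h, the response in PBS-primed WT had 147 genes, and response differences after LPS priming 0 in WT, 1 with the Irf1-/- label and 1 in Ifnar-/-. Without the LPS-primed Ifnar-/- library at 1.5 h, the LPS difference between WT and Ifnar-/- had 421 genes, 203 of them shared with the 209, the response in PBS-primed WT 1686, and response differences 26 in WT (LPS), 1 and 24 with the Irf1-/- label (IFN-γ, LPS). With gene length trends removed, LPS priming in Ifnar-/- gave 387, and response differences after LPS priming 11 in WT, 20 with the Irf1-/- label and 70 in Ifnar-/-. Of 308 list tests fry called 123 and camera with an estimated correlation 69, each of them among the 123. Camera with a preset correlation of 0.01 called 149, of which only 104 were among the 123. On only the compared libraries fry called 64, of which 56 were among the 123. Without the LPS-primed Ifnar-/- library at 1.5 h fry called 133, of which 119 were among the 123. The scaling and dispersions in these fry tests were still those estimated with that library. Lost without it were glycolysis genes for LPS priming in Ifnar-/- (adjusted p = 0.243), TLR4 components for Ifnar-/- against WT after LPS (adjusted p = 0.219), and alternative activation for Ifnar-/- against WT after PBS (adjusted p = 0.0502) and for the LPS difference between WT and Ifnar-/- (adjusted p = 0.0631). Gained were 14. Mitochondrially encoded transcripts passed in 6 comparisons: IFN-γ priming in WT (adjusted p = 0.0117), LPS priming with the Irf1-/- label (0.0164), IFN-γ against LPS in WT (0.0323), that label against WT after PBS (0.0421), the IFN-γ difference between them (0.0124) and the LPS difference between WT and Ifnar-/- (0.00159, from 0.217). Glycolysis genes passed for LPS priming with the Irf1-/- label (0.0164), for that label against WT after LPS (0.0187) and for Ifnar-/- against WT after LPS (0.00546, from 0.134). MHC class II passed for LPS priming in Ifnar-/- (lower, 0.00923) and for Ifnar-/- against WT after PBS (higher, 0.0371), MHC class I for IFN-γ against LPS in WT (0.0479), heat shock genes for the Irf1-/- label against WT after PBS (0.0444) and neutrophil markers for the LPS difference between WT and Ifnar-/- (0.0421). At adjusted p under 0.01 the primings shared 236 genes in WT. For genes called on 2 times and read at the third, 6 of 18 median differences from WT moved by more than 0.1 or changed sign at that threshold. In Ifnar-/- libraries they were -0.671, -0.372 and -0.740 for genes raised by LPS (0, 1.5 and 3 h) and 0.118 in place of -0.0133 for genes lowered by LPS at 1.5 h. With the Irf1-/- label they were -0.407 for genes raised by IFN-γ at 0 h and 0.389 for genes lowered by IFN-γ at 3 h. Depth limits what can be called in genes near 3 counts, which are 0.149 CPM in the median library.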

Other observations

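In this part the values in the next 2 paragraphs were chosen after the data had been seen, and no further test was run on them.

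Mean values of 2 MHC class II transcripts with LPS priming went up in WT and down in the other 2 labels, and the rise of H2-Aa in WT was no longer called without any 1 of the 3 times. H2-Aa went from 15.3 to 20.4 CPM in WT, from 27.6 to 11.03 CPM with the Irf1-/- label and from 19.4 to 11.3 CPM in Ifnar-/- libraries. Cd74 went from 57.8 to 90.5 CPM, from 92.0 to 48.4 CPM and from 75.2 to 63.0 CPM. After IFN-γ priming H2-Aa stood at 73.7 CPM in WT and 94.0 CPM with the Irf1-/- label.

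Ighm fell with LPS priming in 2 of the 3 genotype labels, from 3.01 to 0.279 CPM in WT (-3.40, adjusted p = 5.3e-07) and from 6.02 to 0.616 CPM with the Irf1-/- label, and stood at 8.39 and 9.87 CPM in Ifnar-/- libraries. The B cell receptor gene Cd79a had 20 counts in all libraries together. Il1b was higher in PBS-primed Ifnar-/- libraries than in PBS-primed WT (275 against 49.4 CPM), a call that was lost without the 3 h libraries. Ccl5 had a mean of 663 CPM after LPS priming in Ifnar-/- libraries, with the library that stood apart among them, against 33.1 CPM after PBS. It is not among the rises named above for these libraries, and a contrast with interferon-stimulated genes was not tested. With the Irf1-/- label it stood at 2.40 CPM after IFN-γ priming, against 55.6 CPM in WT.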
